A study of Capra hircus with 10 samples.

How the data were processed

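RNA sequencing was done on mammary gland cells of Lanshan dairy goats grown in 3D culture, from total RNA, per the labels' protocols. The 10 libraries were placed in 5 groups of 2 from the sample titles: Blank, Lv5NC, OV55666 (overexpression of the long noncoding RNA lncRNA55666), Lv3NC and KD553 (its knockdown). Each manipulation was compared with the control that stands just before it in the series text, 5NC before the overexpression and 3NC before the knockdown; the sources do not state this pairing in other words. The titles and the descriptions give different numbers to the KD553 samples, so both KD553 columns were used as libraries of that group without a number, except in the replicate block. Nothing in the labels says that the libraries of a group came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

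The authors deposited FPKM values (fragment counts scaled by transcript length and by the mapped fragments of the library) for 17197 genes, rounded to 2 decimals, per the file headers and the values. The aligner, the quantification tool and the genome build are not given in the sources used here. Of the gene identifiers, 16658 matched an NCBI gene identifier of the RefSeq table for the ARS1.2 assembly, which was used for symbols only, and 539 carry an identifier of the form BGI_novel. No row is named for lncRNA55666, so the level of the targeted RNA is not analysed here and neither the overexpression nor the knockdown could be checked against the labels.

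FPKM values do not keep the number of reads, and the depth of each library is unknown. Relative depths are not analysed here. FPKM summed to between 440565 and 460423 per library.

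Values were analysed as log2(FPKM + 1), with a pseudocount of 1 and no further scaling, for the 11340 genes with an FPKM of at least 1 in at least 2 libraries. Fold changes are therefore on the log2(FPKM + 1) scale, which understates changes of genes with low values. The test was limma 3.58.1 in R 4.3.3 (linear model with a mean for each group, moderated variances with trend and robust options), fitted to all 10 libraries so that the comparisons share 1 estimate of the spread with 5 residual degrees of freedom. p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. The comparisons were OV55666 against Lv5NC, KD553 against Lv3NC, the difference between these effects in a single contrast, each control virus against Blank, and the control viruses against each other. The 95% interval of a log2 change reached 0.245 to either side in the median gene, and 0.347 for the difference between effects.

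The members of 17 lists of pathways and 6 lists of cell type markers, the comparisons of genes, the list tests on both manipulations, the rule for naming genes and most alternatives were chosen before the data were examined. The list tests on the difference between effects and on the comparisons of controls were added after the data had been seen. So were 6 alternatives: Lv5NC as the control of the knockdown, Blank as the control of the lists of both manipulations, a covariate for a deviation shared by libraries, leaving the second Blank library out of other comparisons, replicate blocks with the Lv3NC or the KD553 numbers exchanged, and a different Blank library for each control virus. The 17 lists of either kind with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. The other 6, among them the milk protein genes with 3 tested members, were too short. camera with an estimated correlation and fry were run beside it. fry asks whether the genes of a list move, on balance, in a single direction and does not compare the list with other genes.

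Genes were named by a rule. Among called genes with a symbol for which both libraries of 1 group lay above both of the other, it took the 10 with the largest rise and the 10 with the largest fall for either manipulation, and 5 and 5 in the comparisons of controls. For each list that passed for a manipulation it took up to 4 members with the smallest p in the direction of the list. For milk proteins, milk fat synthesis, prolactin signalling and cell cycle it took up to 3 members with the highest mean where the list did not pass. Not every gene that the rule takes is reported here. Genes named outside this rule are marked as chosen after their values were seen.

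The steps were tested on simulated data with the means and moderated spreads of the 11340 genes, normal noise independent between genes, and 200 genes changed in each of 5 draws. In the comparison of KD553 with Lv3NC 95.8% of genes changed by 1 on the log2 scale were recovered and 54.9% of those changed by 0.5, with a mean of 10.4 wrong calls. In that of OV55666 with Lv5NC the shares were 93.7% and 54.0%, with a mean of 9.4 wrong calls. These shares hold for 200 changed genes, which ease the Benjamini-Hochberg threshold, and for independent noise. They are therefore not the power of the real comparisons, where few or no genes were called. In the data, the largest absolute log2 change of OV55666 against Lv5NC, 1.781, was not called. A list lowered by 0.5 was called in each of 20 draws, and 0.1 other lists were called on average; this does not test lists whose genes vary together. Alternatives tried were another pseudocount, other filters, other scalings, only the groups compared, a replicate block, leaving out each library, a fold threshold and other control groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.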

Results

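Gene expression was measured by RNA sequencing in 10 libraries of goat mammary gland cells kept in 3D culture. The study asked what raising or lowering lncRNA55666, delivered with a virus, does to these cells. Each of the 5 groups (Blank, Lv5NC, OV55666, Lv3NC and KD553) had 2 libraries. Between 10922 and 11163 genes per library had an FPKM of at least 1, and the depth in reads is unknown. Across genes, the libraries of a group correlated with r between 0.990 and 0.994 on the log2 scale.

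The cells of every group had high levels of fibroblast and mesenchymal genes and almost no RNA of epithelial marker genes. The collagen genes COL1A1 and COL1A2 had mean FPKM of 5144 and 3886 over the 10 libraries, COL3A1 2846, the matrix proteoglycan DCN 2113 and LUM 1415. VIM, a filament protein of mesenchymal cells, lay between 3735 and 7344. All 12 fibroblast markers were above 1 FPKM in every library. Of 17 luminal epithelial markers in the table, 14 were below 1 FPKM in every library, among them the keratin genes KRT8 (at most 0.02) and KRT18 (at most 0.51), EPCAM (at most 0.02) and CDH1 (at most 0.01). The 3 that reached 1 FPKM were ESR1 (mean 9.03), SPINT2 (mean 4.88) and CLDN4 (at most 1.04). Of 10 basal or myoepithelial markers, the smooth muscle genes ACTA2 (mean 859), TAGLN (mean 805) and MYLK (mean 282) were high, whereas KRT14 and TP63 were at most 0.09 and 0.05. Of the 19 milk protein genes listed, only 10 had a row under their symbol. CSN1S1, CSN1S2, CSN2 and LALBA had none, so their levels are unknown. Most of the 10 were near the floor: 7, CSN3 with at most 0.05 among them, were below 1 FPKM in every library. MFGE8 (mean 105.6) and SPP1 (mean 16.6) were the exceptions with levels above 2. Of the markers of endothelial cells 9 of 11, of leukocytes 12 of 14 and of adipocytes 7 of 8 were below 1 FPKM in every library. These genes were picked from the marker lists, which were fixed beforehand, after their values were seen.

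**Figure D1:**
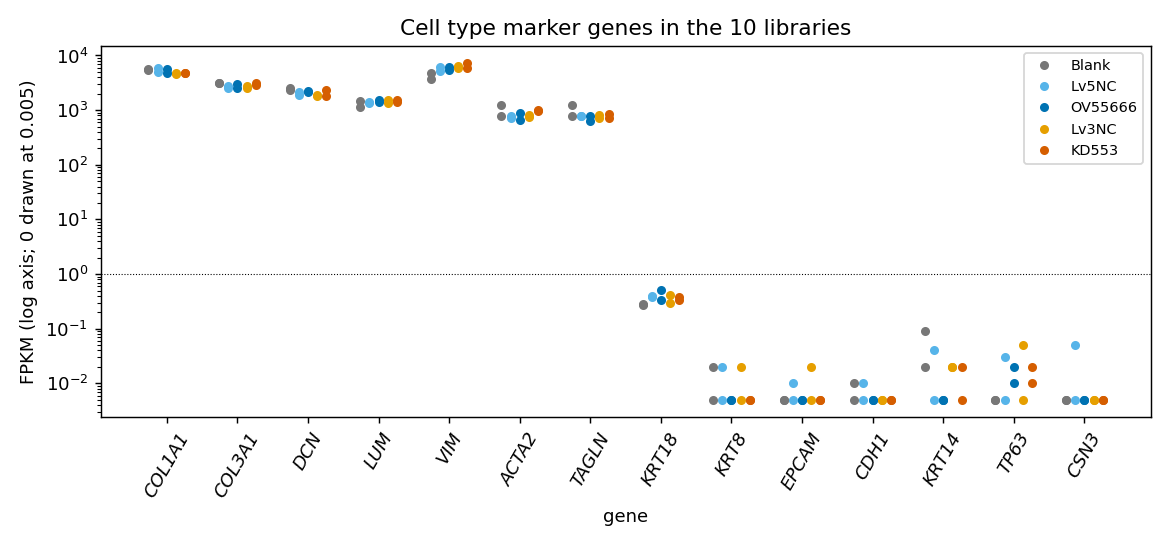
FPKM of 14 marker genes on a log axis, with 1 point per library coloured by group and values of 0 drawn at 0.005; the dotted line marks 1 FPKM. COL1A1 to TAGLN lie between 623 and 7344 FPKM in all 10 libraries, and KRT18 to CSN3 lie below 1 in all 10.

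In cells with lncRNA55666 overexpression, no single gene passed the test against Lv5NC. With limma, 0 of 11340 genes had an adjusted p under 0.05, and 166 genes had an unadjusted p under 0.05, where 567 are expected by chance. The count also fell short of 567 in the contrast of both effects and between the control viruses. The 567 is therefore only a rough mark in every comparison here, and the cause was not tested. None of the milk protein and milk fat genes named here passed the test. MFGE8 was at 108.5 ± 4.0 FPKM (SD, n = 2) against 111.8 ± 3.2, and XDH at 1.23 ± 0.23 against 1.32 ± 0.52. SPP1 was at 15.8 ± 2.7 against 20.1 ± 1.9 (log2 −0.33 ± 0.20, SE), with both OV55666 libraries below both Lv5NC libraries. PLIN2, which coats lipid droplets, was at 61.5 ± 12.2 against 60.4 ± 2.7, IDH1 at 40.7 ± 4.0 against 38.6 ± 1.4 and ELOVL5, a fatty acid elongase, at 32.6 ± 0.6 against 31.2 ± 0.2. In the signalling list, AKT1 was at 82.1 ± 1.2 against 86.0 ± 3.0 FPKM, SOCS2 at 25.4 ± 2.1 against 28.4 ± 4.2 and IGFBP5 at 40.6 ± 6.1 against 50.6 ± 21.2.

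As a group, cell cycle genes were lower with overexpression: all 37 tested members lay below their level in Lv5NC, with a median log2 change of −0.20 (camera adjusted p = 5.83e-16), although 0 passed alone over all genes and 0 adjusted over the list alone. With an estimated correlation, 0.742 for this list, its adjusted p was 0.866. The cyclins CCNA2 and CCNB2 were at 4.11 ± 0.06 and 3.73 ± 0.09 FPKM against 5.85 ± 1.46 and 5.39 ± 0.82, UBE2C at 11.6 ± 1.4 against 14.7 ± 2.3 and MYBL2 at 7.88 ± 0.83 against 10.8 ± 2.8. The difference rested largely on the first Lv5NC library, without which the median was −0.04 (adjusted p = 0.0178). Against Blank the list did not pass, and 28 of 37 members were higher (median 0.0687, adjusted p = 0.263). Immediate early genes, induced within minutes of a stimulus, were lower in 13 of 20 members, with a median of −0.07 (camera adjusted p = 0.0285, and adjusted p = 0.866 with an estimated correlation), and 0 fell adjusted over the list alone. EGR3 was at 2.49 ± 0.07 against 3.33 ± 0.32 FPKM, FOSB at 282.2 ± 51.6 against 310.0 ± 9.7, MYC at 22.6 ± 4.9 against 25 ± 1.1 and NR4A1 at 95.5 ± 8.6 against 124.9 ± 44.9. That call was lost without the first Lv5NC library (median 0.01, adjusted p = 0.960) and without the second OV55666 library (adjusted p = 0.186), and against Blank the list was higher (median 0.191, adjusted p = 0.00642; 0.388 as adjusted p with an estimated correlation). The other 15 lists did not pass (adjusted p between 0.0788 and 0.978). The cholesterol synthesis list had a median of −0.01 and a mean of 0.01 and the milk fat list a median of 0.03. The prolactin signalling list, which also covers growth hormone and STAT5, had a median of 0.03 and a mean of −0.01 (camera adjusted p = 0.808 for each). In every comparison the milk fat list was tested without DGAT2, PPARG, THRSP, LPL and SLC27A6 (at most 0.14 FPKM). The signalling list was tested without the prolactin receptor gene PRLR, PGR and ELF5 (at most 0.21 FPKM). These genes near the floor were named after their values were seen. Interferon response genes (median 0.08, adjusted p = 0.0788) passed without the second Lv5NC library (median 0.16, adjusted p = 0.000392) and without the first OV55666 library (median 0.16, adjusted p = 0.000267). In 6 of the 15 the median, the mean and the test differed in sign.

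The knockdown libraries differed from Lv3NC in 8 genes, 5 higher and 3 lower. CH25H (gene 102191759), a hydroxylase that oxidises cholesterol, rose from 2.77 ± 0.62 to 9.38 ± 0.28 FPKM (SD, n = 2), a log2 change of 1.47 ± 0.13 (SE, adjusted p = 0.01). PRELP (gene 102183894), a proteoglycan of the matrix, rose from 13.1 ± 2.4 to 29.0 ± 0.04 FPKM (log2 1.10 ± 0.13, adjusted p = 0.0237). HSPB6 (gene 102172571), a small heat shock protein, rose from 57.2 ± 6.8 to 118.1 ± 4.5 (log2 1.04 ± 0.10, adjusted p = 0.0134). WISP2 (gene 102184354), a secreted matricellular protein, rose from 1.14 ± 0.06 to 2.80 ± 0.17 FPKM (log2 0.83 ± 0.10, adjusted p = 0.0354). The homeobox gene MSX2 (gene 102169797) rose from 20.2 ± 1.9 to 32.7 ± 0.4 (log2 0.67 ± 0.09, adjusted p = 0.0454). The sphingosine phosphate receptor gene S1PR2 (gene 102180585) fell from 16.1 ± 0.1 to 9.04 ± 0.98 FPKM (log2 −0.77 ± 0.10, adjusted p = 0.0470). GSPT1 (gene 102169540), a factor of translation termination, fell from 56.2 ± 1.9 to 33.8 ± 1.7 (log2 −0.72 ± 0.07, adjusted p = 0.0161). KCTD3 (gene 102173767) fell from 13.8 ± 0.2 to 8.78 ± 0.16 (log2 −0.60 ± 0.07, adjusted p = 0.0237). In all 8, both KD553 libraries lay outside the range of the other 8 libraries, which was so for 9.74% of all tested genes, where chance gives 4.44%. The 8 genes were called on the same KD553 values, so this is no separate support for them. The unadjusted p was under 0.05 for 853 genes, where 567 are expected by chance.

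The number of calls depended on the libraries and terms in the fit. With the column numbers as a replicate block it was 1, and with the KD553 numbers exchanged 5, with 1 and 4 of the 8 among them. It was 0 with either KD553 library left out, 2 without the first Lv3NC library, 3 without the second, and 0 in a fit of only the groups compared. Against Lv5NC it was 2 (HSPB6 and GSPT1) and against Blank 286, which hold all 8. It was 12 without the second Blank library, 7 of them among the 8, and 11 against the mean of both control viruses, which hold all 8.

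**Figure D2:**
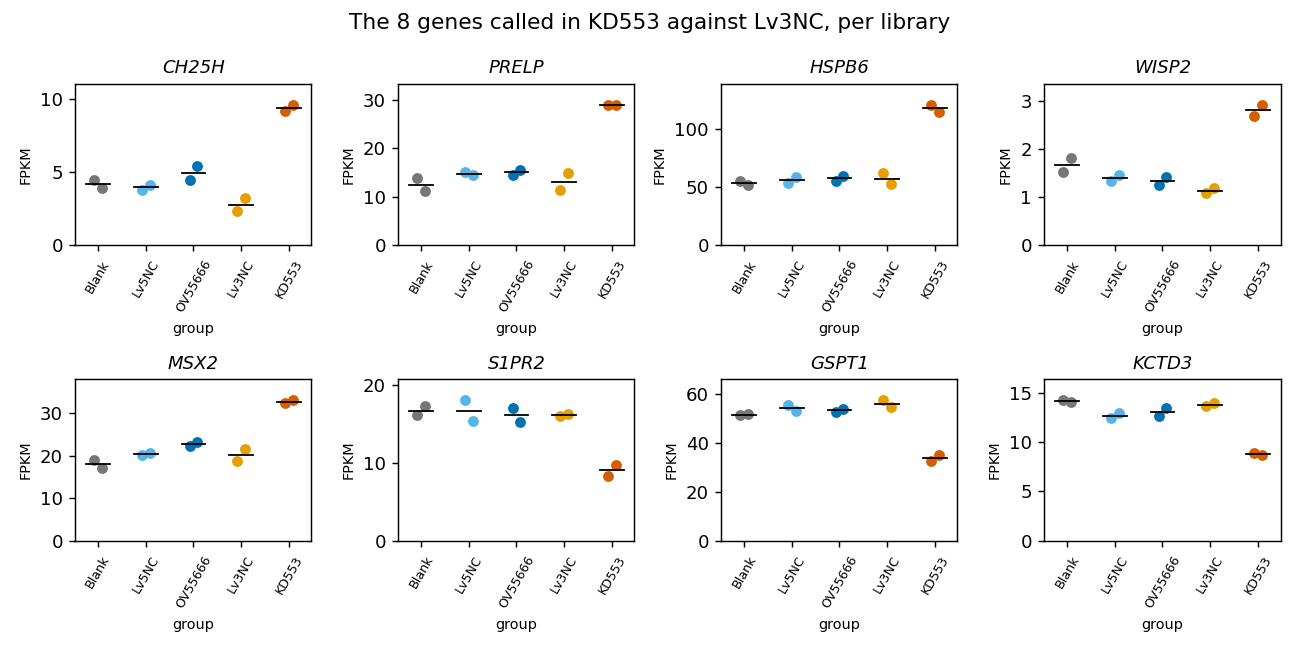
FPKM of the 8 genes called in KD553 against Lv3NC, with 1 panel per gene, 1 point per library and a line at each group's mean of 2; axes start at 0. The KD553 points lie above the other 8 libraries for CH25H, PRELP, HSPB6, WISP2 and MSX2 and below them for S1PR2, GSPT1 and KCTD3.

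As a group, cholesterol synthesis genes were lower in the knockdown than in Lv3NC. All 22 tested members were lower, with a median log2 change of −0.55 (camera adjusted p = 5.91e-20; adjusted p = 0.398 with an estimated correlation, 0.702 for this list). None passed over all genes, and 12 fell adjusted over the list alone. HMGCS1, a synthase of the mevalonate pathway, was at 29.6 ± 2.3 FPKM against 58.0 ± 12.9, and MVK at 4.01 ± 0.03 against 6.83 ± 0.76. EBP was at 22.5 ± 1.4 against 30.8 ± 1.6. The control mattered: against Lv5NC the median was −0.13 (adjusted p = 0.00593; 0.926 as adjusted p with an estimated correlation), and the Lv5NC libraries had HMGCS1 at 35.3 and 39.1 FPKM where the Lv3NC libraries had 67.1 and 48.9. Of the milk fat synthesis genes, 17 of 26 were lower in the knockdown (median −0.05, camera adjusted p = 0.0124; adjusted p = 0.525 with an estimated correlation), with 0 adjusted over the list alone. In that list FASN, the fatty acid synthase, was at 14 ± 0.2 FPKM against 21.5 ± 5.7, ACACA, which supplies its substrate, at 6.83 ± 0.04 against 8.86 ± 0.65, ELOVL6 at 8.58 ± 1.03 against 11.3 ± 2.0 and FABP3 at 1.16 ± 0.32 against 3.33 ± 1.91. The milk fat call was lost without the first Lv3NC library (adjusted p = 0.127), without 1 of the KD553 libraries (adjusted p = 0.314) and against Lv5NC (adjusted p = 0.629). Among milk protein genes, MFGE8 was at 114.5 ± 3.9 against 99.8 ± 3.8 FPKM and SPP1 at 11.8 ± 3.9 against 19.5 ± 0.05, neither past the test (adjusted p = 0.761 and 0.405). XDH was at 1.42 ± 0.59 against 1.23 ± 0.06. Of the prolactin signalling list, which had a camera adjusted p of 0.994 and a median of −0.02, AKT1 was at 86.3 ± 0.7 against 87.7 ± 3.1 FPKM, SOCS2 at 26.0 ± 5.1 against 28.9 ± 0.2 and IGFBP5 at 27.6 ± 27.0 against 22.4 ± 12.3.

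As a group, inflammatory targets of NF-kB were higher in the knockdown than in Lv3NC. Of 18 tested members 16 were higher, with a median log2 change of 0.37 (camera adjusted p = 1.93e-08; adjusted p = 0.141 with an estimated correlation). None passed over all genes, and 3 rose adjusted over the list alone. The cytokine IL6 was at 4.68 ± 1.63 FPKM against 1.12 ± 0.54 in Lv3NC, and the chemokine CXCL8 at 10 ± 5.7 against 2.46 ± 0.61. The adhesion molecule ICAM1 was at 1.95 ± 0.40 against 0.68 ± 0.30 and CCL20 at 3.02 ± 0.35 against 1.55 ± 0.48. This list and the cholesterol list passed with each library of the comparison left out, with medians from 0.302 to 0.466 and from −0.729 to −0.390, and this list also passed against Lv5NC, with a smaller median of 0.22 (adjusted p = 0.0203; 0.926 as adjusted p with an estimated correlation).

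Cell cycle genes were lower in the knockdown in 36 of 37 members (median −0.27, camera adjusted p = 2.05e-08; adjusted p = 0.525 with an estimated correlation), with UBE2C at 11.3 ± 2.4 FPKM against 15.6 ± 1.3. The replication genes MCM7 and PCNA were at 22.7 ± 3.4 and 13.6 ± 2.1 against 28.6 ± 1.1 and 16.5 ± 1.3, and CCNB1 at 9.13 ± 3.15 against 12.1 ± 1.8. The KD553 libraries differed from each other in this list: leaving out 1 of them gave a median of −0.02 (adjusted p = 0.955), leaving out the other −0.49, and against Blank the list was higher, with a median of 0.17 (adjusted p = 0.00818; 0.711 as adjusted p with an estimated correlation). Interferon response genes were higher in 22 of 27 (median 0.18, adjusted p = 0.000376; 0.525 as adjusted p with an estimated correlation), and the call was lost without 1 KD553 library (adjusted p = 0.446). PARP9 was at 2.78 ± 0.16 against 1.96 ± 0.13 FPKM, PARP14 at 2.97 ± 0.26 against 2.10 ± 0.16, PSMB8 at 4.12 ± 0.84 against 2.94 ± 0.36 and IFI44L at 4.51 ± 0.80 against 3.28 ± 0.01. Immediate early genes were higher in 18 of 20 (median 0.21, adjusted p = 0.00134; 0.525 as adjusted p with an estimated correlation), with KLF4 at 83.3 ± 0.4 against 64.7 ± 4.4 FPKM, FOSB at 327 ± 12 against 261 ± 20, BTG2 at 30.8 ± 5.5 against 24.4 ± 0.8 and JUNB at 110.2 ± 10.7 against 94.7 ± 0.7. This call was lost without the other KD553 library (adjusted p = 0.314) and without the first Lv3NC library (adjusted p = 0.0541). Fibroblast markers were higher in 10 of 12 (median 0.09, adjusted p = 0.0221; 0.525 as adjusted p with an estimated correlation), where 1 gene, THY1, rose adjusted over the list alone, at 172.9 ± 11.7 against 123.5 ± 5.0 FPKM. FBLN1 was at 5.96 ± 0.91 against 3.25 ± 0.54, COL3A1 at 3045 ± 157 against 2650 ± 211 and MFAP5 at 344.7 ± 43.5 against 277.8 ± 41.6. Genes of oxidative phosphorylation were lower in 15 of 19 (median −0.09, adjusted p = 0.0221; 0.636 as adjusted p with an estimated correlation), with ATP5A1 at 145.5 ± 1.9 against 169.9 ± 9.3 FPKM, ATP5B at 194.7 ± 4.9 against 215.8 ± 3.8, NDUFB3 at 29.6 ± 1.7 against 34.5 ± 3.6 and NDUFA1 at 41.4 ± 1.6 against 45.5 ± 1.8. The fibroblast call was lost without 1 KD553 library (adjusted p = 0.519) and without the first Lv3NC library (adjusted p = 0.127), and that of oxidative phosphorylation without either KD553 library (adjusted p = 0.0751 and 0.158) and without the second Lv3NC library (adjusted p = 0.205). Against Lv5NC the interferon, immediate early, fibroblast and oxidative phosphorylation lists did not pass (adjusted p between 0.0609 and 0.710). Against Blank the fibroblast median turned to −0.17 and that of oxidative phosphorylation to 0.0289 (camera adjusted p = 0.41 and 0.473). The interferon and immediate early medians stayed above 0 there, at 0.165 and 0.288. Except for THY1, no gene of the cell cycle, interferon, immediate early, fibroblast and oxidative phosphorylation lists passed adjusted over the list alone. The other 9 lists did not pass (adjusted p between 0.170 and 0.994); in 3 of them the median, the mean and the test differed in sign.

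**Figure D3:**
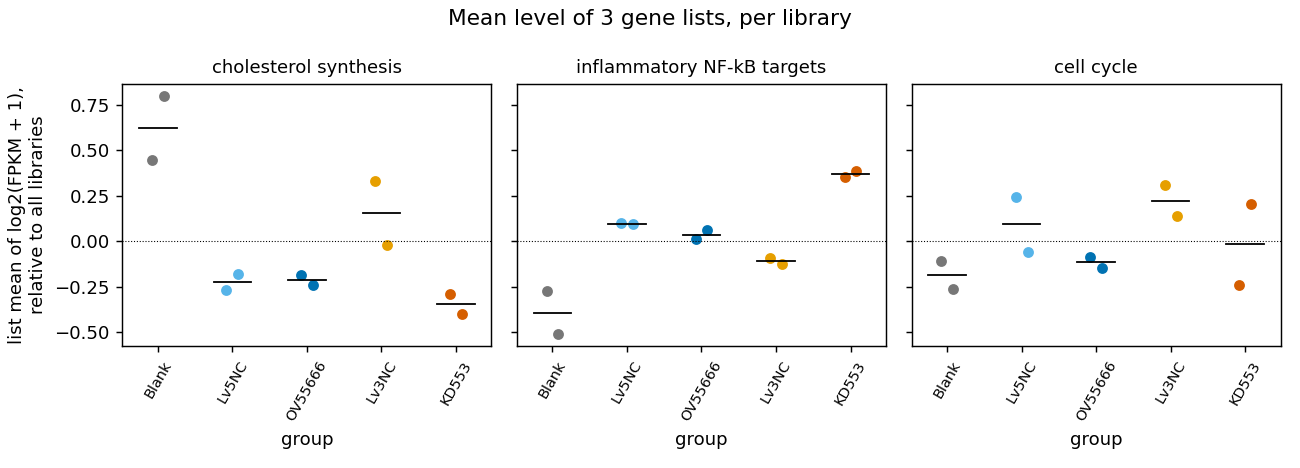
Mean log2(FPKM + 1) of the tested members of 3 gene lists in each library, relative to the mean of all 10 libraries, with 1 point per library and a line at each group's mean of 2. The cholesterol list is highest in Blank, at 0.449 and 0.802, and lowest in KD553, at −0.291 and −0.402; the NF-kB list is lowest in Blank and highest in KD553.

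The measured log2 changes of overexpression and knockdown were not opposite across the transcriptome. Over the 11340 genes they correlated weakly and positively (Pearson r = 0.165, Spearman rho = 0.175), and 56.1% of genes had the same sign. Genes are not independent replicates. No gene was called for overexpression, so its changes may be mostly spread between libraries. The correlation therefore cannot exclude opposite effects of raising and lowering the RNA. In the contrast of both effects limma called 0 genes, with 386 at an unadjusted p under 0.05, where 567 are expected by chance. By lists, cholesterol synthesis was higher in the overexpression effect than in the knockdown effect in all 22 members (median difference 0.54, camera adjusted p = 3.31e-17; adjusted p = 0.335 with an estimated correlation) and NF-kB targets were lower in all 18 (median −0.40, adjusted p = 2.55e-10; 0.0910 as adjusted p with an estimated correlation). Without the second Lv5NC library the NF-kB median was −0.243. In OV55666 against Lv5NC alone, the cholesterol and NF-kB medians were −0.012 and −0.0282, and neither list passed.

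The control viruses were compared with Blank to measure what virus delivery alone goes with. Lv5NC differed from Blank in 33 genes, 15 higher and 18 lower, and Lv3NC in 15, 3 higher and 12 lower. In Lv5NC, the prostaglandin synthase gene PTGS2 rose from 21.9 ± 7.0 to 62.3 ± 5.8 FPKM (SD, n = 2; log2 1.5 ± 0.21, SE), and CCL20 from 0.44 ± 0.49 to 2.68 ± 0.30. The growth factor gene EREG rose from 5.02 ± 1.17 to 14.4 ± 0.6, the transcription factor gene TBX3 from 4.38 ± 0.92 to 10.9 ± 1.5 and GLDN from 5.08 ± 1.14 to 11.4 ± 1.9 (limma adjusted p between 0.0115 and 0.0463). The small GTPase gene RRAD fell from 7.35 ± 1.07 to 1.01 ± 0.28 FPKM (log2 −2.06, adjusted p = 0.0164). In the same comparison, the sterol reductase gene TM7SF2 fell from 4.17 ± 0.89 to 0.785 ± 0.431, LRRC17 from 6.10 ± 0.69 to 1.46 ± 0.08 and the cysteine dioxygenase gene CDO1 from 21.4 ± 3.2 to 7.12 ± 0.89. In Lv3NC, EREG rose to 11 ± 0.1 FPKM, ANKRD28 from 9.45 ± 0.49 to 18.1 ± 1.2 and FAM65B from 2.71 ± 0.37 to 5.27 ± 0.34. RRAD fell to 1.40 ± 0.35, LRRC17 to 1.33 ± 0.30, CDO1 to 8.30 ± 0.25, and GPM6B from 2.14 ± 0.25 to 0.205 ± 0.148 (adjusted p between 0.0349 and 0.0395).

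Both control viruses called 11 genes in common, 3 higher and 8 lower. Independent lists would share 0.00397 and 0.0190, but these lists share the Blank libraries. Simulated groups without effect against a simulated shared Blank had 0 in common. The log2 changes of the control viruses correlated across genes with r = 0.857 against 0.502 in the simulation. Their covariance was 0.0518 against 0.0101, and 80.3% of genes had the same sign against 66.7%. The simulation holds a shared control but no effects, with genes drawn independently and the same spread in all groups. The Blank libraries differed most from each other, by a median of 0.145 on the log2 scale against 0.0953 to 0.125 in other groups. The simulated values may therefore understate what the shared Blank gives. With a different Blank library for each control virus, the correlation was 0.606 or 0.510 and the covariance 0.0409 or 0.0368. The same-sign share was 58.5% or 61.4%. Which value held depended on which virus took which library. The simulated values share a Blank and are no mark for these. With independent noise, no effect and no shared library, the changes would not correlate on average. The number of shared calls cannot be judged from those fits, which have only 1 Blank library on each side. Against the first Blank library alone few genes were called with either virus, so few could be shared. Part of the excess of the shared calls may still come from the shared controls. The counts depended on the Blank libraries: without the first, 288 genes were called in Lv5NC and 292 in Lv3NC, without the second 3 and 1, and 0 with any control virus library left out. The second Blank library stood apart, with 23.5% of its FPKM in its 10 highest genes against 17.7% to 20.8% in the other 9.

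As a group, cholesterol synthesis genes were lower with both control viruses. In Lv5NC all 22 members were lower than in Blank (median −0.83, camera adjusted p = 3.33e-27; adjusted p = 0.156 with an estimated correlation), 7 over all genes and 22 adjusted over the list alone. In Lv3NC all 22 were lower too (median −0.41, camera adjusted p = 2.62e-13; adjusted p = 0.216 with an estimated correlation), 0 over all genes and 16 adjusted over the list alone. With a library left out the Lv3NC median ran from −0.619, without the first Blank library, to −0.283. Milk fat synthesis genes were lower in Lv5NC in 22 of 26 members and in Lv3NC in 20 (medians −0.34 and −0.20). Over all genes limma called 0 of them in either, while 13 and 2 fell and 1 and 0 rose adjusted over the list alone. Of the NF-kB targets 15 of 18 were higher with either virus (medians 0.39 and 0.27). Over all genes 2 of them rose in Lv5NC, PTGS2 and CCL20, and 0 in Lv3NC, while 9 and 4 rose and 1 and 2 fell adjusted over the list alone. Cell cycle genes were higher in 36 and 37 of 37 members (medians 0.27 and 0.42), of which 0 passed over all genes and 0 adjusted over the list alone. Heat shock and oxidative stress genes were higher in 19 and 18 of 20 (medians 0.23 and 0.22), of which 1 and 0 rose over all genes and 6 and 4 adjusted over the list alone. The 1 was TXNRD1, at 60.2 ± 0.8 FPKM in Lv5NC against 31.5 ± 7.0, which was chosen after its value was seen. In these 4 lists the camera adjusted p was at most 0.00198, and with an estimated correlation the adjusted p was between 0.156 and 0.445 in Lv5NC and between 0.216 and 0.348 in Lv3NC. Some of these medians rested on 1 library. Without the second Blank library the NF-kB medians were 0.193 in Lv5NC and 0.181 in Lv3NC and the heat shock median in Lv5NC was 0.149. The cell cycle median in Lv5NC was 0.119 without the first Lv5NC library, and the milk fat median in Lv3NC was −0.135 without the second Lv3NC library.

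Basal or myoepithelial markers were lower in Lv5NC and Lv3NC than in Blank (medians −0.41 and −0.37, camera adjusted p = 0.0144 and 0.00845; 0.232 and 0.216 as adjusted p with an estimated correlation), with 0 and 2 of the 5 tested that fell adjusted over the list alone. The 5 were the smooth muscle genes ACTA2, TAGLN, MYLK, CNN1 and MYH11. KRT14, TP63, ITGA6, COL17A1 and OXTR were below 1 FPKM in every library and not tested. The lower list therefore does not show fewer basal epithelial cells. With a library left out the medians of this list ran from −0.741 to −0.146 in Lv5NC and from −0.707 to −0.0986 in Lv3NC. Both calls were lost without the second Blank library (medians −0.146 and −0.0986), which had CNN1 at 46.2 FPKM where the other 9 libraries had 5.8 to 19.7. That library also ended the milk fat call in Lv3NC when left out. In all, 9 lists passed in Lv5NC and 10 in Lv3NC. Lower in both were hypoxia and glycolysis (medians −0.22 and −0.15, adjusted p = 7.02e-05 and 5.1e-05; 0.232 and 0.216 as adjusted p with an estimated correlation) and fibroblast markers (medians −0.25 and −0.25, adjusted p = 0.0275 and 0.0022; 0.311 and 0.216 as adjusted p with an estimated correlation). Immediate early genes were higher in both (medians 0.22 and 0.11, adjusted p = 8.24e-05 and 0.0345; 0.232 and 0.450 as adjusted p with an estimated correlation), with a median in Lv5NC of 0.081 without the first Lv5NC library. Oxidative phosphorylation was higher in Lv3NC (median 0.10, adjusted p = 0.00591; 0.481 as adjusted p with an estimated correlation), with a median of 0.234 without the first Blank library. Without that library the hypoxia medians were −0.397 in Lv5NC and −0.284 in Lv3NC. With the second Blank library left out, hypoxia was lost in both, fibroblast markers in Lv5NC and oxidative phosphorylation in Lv3NC. Basal and fibroblast markers in Lv5NC were also lost without the first Lv5NC library. The immediate early call in Lv3NC was lost without the first Blank library (median 0.217) and without the second Lv3NC library, where the median turned to −0.0178.

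The control viruses did not differ from each other in any single gene: limma called 0, with 303 genes at an unadjusted p under 0.05, where 567 are expected by chance. Cholesterol synthesis genes were lower in Lv5NC than in Lv3NC in all 22 members (median −0.40, camera adjusted p = 4.13e-19; adjusted p = 0.284 with an estimated correlation), with 6 adjusted over the list alone. NF-kB targets were higher in Lv5NC in 12 of 18 (median 0.16, adjusted p = 0.000129; 0.284 as adjusted p with an estimated correlation), with 1 adjusted over the list alone. Both calls held with each library left out, with medians from −0.562 to −0.21 and from 0.145 to 0.18. The −0.21 came without the first Lv3NC library. In all 7 lists passed, and the other 5 (milk fat synthesis, cell cycle, extracellular matrix, oxidative phosphorylation and immediate early genes, adjusted p between 0.000924 and 0.0209; between 0.284 and 0.740 as adjusted p with an estimated correlation) were each lost without at least 1 library. The cell cycle median turned to 0.0192 without the second Lv5NC library and the immediate early median to −0.00157 without the first. With an estimated correlation no list passed in any of the 6 comparisons, and with fry none did except cholesterol synthesis, milk fat synthesis and NF-kB targets in Lv5NC against Blank (adjusted p = 0.0156 for each).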

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

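The list tests on the difference between effects and the tests of explanations were chosen only after the results were seen. In 5 lists the effect of overexpression differed from that of the knockdown in the contrast of both effects: cholesterol synthesis (median log2 difference 0.544), inflammatory NF-kB targets (−0.398), immediate early genes (−0.308), oxidative phosphorylation (0.123) and milk fat synthesis (0.116). The camera adjusted p ran from 3.31e-17 to 0.00686, and with an estimated correlation the adjusted p ran from 0.0910 to 0.642. In OV55666 against Lv5NC alone, the medians of these 5 lists in the same order were −0.012, −0.0282, −0.0708, 0.0543 and 0.0344. Of the 5, only immediate early genes passed there. For cholesterol synthesis and NF-kB targets the difference therefore lay mostly in KD553 against Lv3NC. With each of the 8 libraries left out in turn, 4 of the lists passed each time, but the sizes moved: cholesterol synthesis from 0.38 to 0.698, NF-kB targets from −0.478 to −0.243, immediate early genes from −0.405 to −0.117 and oxidative phosphorylation from 0.0825 to 0.159. The −0.243 came without the second Lv5NC library and the −0.117 without 1 KD553 library. Milk fat synthesis, with medians from 0.0991 to 0.2, was lost without the first Lv3NC, the first Lv5NC or the same KD553 library. With 2 libraries in a group, no library could be tested for standing apart from its group.

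The lower cholesterol synthesis list in KD553 than in Lv3NC may come from the Lv3NC side as well as from the knockdown. By list mean, KD553 lay below Lv3NC by 0.502 on the log2 scale, with a 95% interval for the difference from −0.926 to −0.0769. Against Lv5NC the difference was −0.125, with an interval from −0.549 to 0.3, which holds both 0 and the value against Lv3NC. A high Lv3NC control and a knockdown effect therefore cannot be told apart with 2 libraries in each group. Against Blank the list mean was lower by −0.47 in Lv3NC, −0.847 in Lv5NC and −0.972 in KD553. For NF-kB targets it was higher in the same order, by 0.283, 0.488 and 0.761. In both lists KD553 thus differed from Lv3NC in the direction in which the control viruses differed from Blank. The cause of this order was not tested. Fewer dividing cells stay open too: with the cell cycle list mean of each library as a covariate the difference was −0.548, which is not smaller, while its interval, −1.13 to 0.0307, held 0. That interval is wider because the SE was 0.208 in place of 0.165 and the covariate took 1 degree of freedom. The KD553 library with the higher cell cycle mean (0.208, above the second Lv3NC library at 0.139) had the lower cholesterol mean (−0.402), which goes against this explanation, but a single library does not exclude it. An effect of lowering lncRNA55666 itself stays among the open explanations and was not tested, because no row of the table is named for that RNA, although an unnamed gene of the table could be it.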

How the results depend on the processing

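Lv5NC as the control of the knockdown, Blank as the control of the lists of both manipulations, the covariate, the crossed block, the block with the KD553 numbers exchanged and leaving the second Blank library out of the comparisons of manipulations were chosen only after the result was seen. The covariate was the first component of the deviations from the group means, estimated from the libraries it then adjusts, and this favours high counts. Unless a reason is given, the cause was not tested.

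In OV55666 against Lv5NC the count of 0 genes held in the other settings except a pseudocount of 0.1, which gave 1, and Blank as control, which gave 43. The number of its lists, 2, was 1 with no filter, 1 with an FPKM of at least 5, 1 after quantile normalization, 5 with only the groups compared, 8 with Blank as control, 0 with an estimated correlation, 0 with fry, 0 with the covariate and an estimated correlation, and 1 to 3 with a library left out.

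In KD553 against Lv3NC the 8 genes became 0 with only the groups compared, which leaves 2 residual degrees of freedom, 3 at an absolute log2 change of at least 1, 28 with the covariate, 286 with Blank as control, 2 with Lv5NC as control, and 0 to 3 with a library of these groups left out. Without the second Blank library it was 12, with 7 of the 8 among them, and against the mean of both control viruses 11, with all 8. A single library left in a group was assumed to vary like the other groups. The count was 7 to 9 under the other pseudocount, filters and scalings, but the genes changed. Of the 8, 5 were called with no filter and 6 after quantile normalization. It was 7 of the 8 with median-of-ratios scaling, with an FPKM of at least 5 and after rescaling, and all 8 with a pseudocount of 0.1. The 8 lists became 3 with Lv5NC as control, 0 with an estimated correlation, 0 with fry, 0 with the covariate and an estimated correlation, and 4 to 7 with a library left out. The difference between effects, with 0 genes, had 2 with the covariate.

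In Lv5NC against Blank the 33 genes became 18 with a pseudocount of 0.1, 13 with no filter, 12 after rescaling to a common sum, 15 at an absolute log2 change of at least 1, 2 with a replicate block, 418 with the covariate and 0 to 288 with a library left out. In Lv3NC against Blank the 15 became 6 with a pseudocount of 0.1, 7 with no filter, 8 with an FPKM of at least 5, 8 after rescaling, 7 with median-of-ratios scaling, 56 with only the groups compared, 9 at an absolute log2 change of at least 1, 6 with the block, 402 with the covariate and 0 to 292 with a library left out. Lv5NC against Lv3NC, with 0 genes, had 1 with no filter. The replicate block by title numbers covered the 8 libraries other than KD553, and with it OV55666 against Lv5NC and Lv5NC against Lv3NC stayed at 0. The numbers of the KD553 columns match the titles of the samples but not their descriptions, so both pairings were fitted, after the results were seen. In KD553 against Lv3NC the 8 genes became 1 with the column numbers as a replicate block and 5 with the KD553 numbers exchanged, with 1 and 4 of the 8 among them. Its 8 lists and the 0 genes of the difference between effects stayed with either.

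Of the genes named, 14 values turned direction with a library left out and 23 under other settings, none of them a called gene. In OV55666 against Lv5NC PLIN2 ran from −0.19 to 0.21 on the log2 scale with a library left out, NR4A1 from −0.71 to 0.0327, XDH from −0.27 to 0.19, IGFBP5 from −0.69 to 0.18, FOSB from −0.33 to 0.0397, MYC from −0.37 to 0.0602 and IDH1 from −0.0246 to 0.17. PLIN2 was −0.00809 with median-of-ratios scaling. With Blank as control CCNA2 was 0.0459, CCNB2 0.0755, EGR3 0.51, FOSB 0.73, NR4A1 0.86, MFGE8 0.22, XDH 0.56, IDH1 −0.11, ELOVL5 −0.0386 and SOCS2 0.20. With the mean of both control viruses NR4A1 was 0.0316, MFGE8 0.0380, ELOVL5 −0.00233 and IGFBP5 0.34.

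In KD553 against Lv3NC XDH ran from −0.15 to 0.35 with a library left out, SOCS2 from −0.36 to 0.0349, IGFBP5 from −1.19 to 1.14 and AKT1 from −0.0570 to 0.0135. With Blank as control PCNA was 0.12, CCNB1 0.0665, ATP5B 0.0290, FBLN1 −0.14, COL3A1 −0.0462, AKT1 0.0150 and SOCS2 0.22, and with Lv5NC as control AKT1 was 0.00464. The files hold no read counts, so what depth limits could not be computed.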

Other observations

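The genes and tests in this part were chosen after the values were seen. The fatty acid desaturase genes SCD and FADS2, members of the milk fat list, were highest in Blank and next in Lv3NC, as the mean of the cholesterol list was; the order of the other 3 groups differed. SCD was at 31.2 ± 16.0 FPKM in Blank (SD, n = 2), 15.6 ± 4.9 in Lv3NC, 8.22 ± 0.86 in KD553, 7.93 ± 3.06 in OV55666 and 7.82 ± 0.18 in Lv5NC, and FADS2 at 12.6 ± 5.7, 4.96 ± 0.39, 1.75 ± 0.73, 3.02 ± 1.71 and 3.11 ± 1.64. Neither passed in Lv5NC against Blank (limma adjusted p = 0.118 for SCD and 0.152 for FADS2) or in KD553 against Lv3NC (0.684 and 0.602).

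The share of tested genes whose 2 libraries of a group both lay outside the range of the other 8 was 14.9% for Blank, 9.74% for KD553, 3.83% for Lv3NC, 3.22% for Lv5NC and 2.13% for OV55666, where chance gives 4.44%. With Lv5NC in place of Lv3NC, the log2 changes of the 8 genes called in the knockdown were between 0.66 and 1.07 for the 5 that rose and between −0.81 and −0.48 for the 3 that fell. The second Blank library had 12.6% of its FPKM in 2 genes, which held 6.18% to 8.17% in the other 9 libraries, and MYLK at 553 FPKM, where the other 9 had 208 to 304.

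Libraries of a group differed along an axis shared between groups. The first component of the deviations from the group means held 47.7% of their variance and set the first Lv5NC, the first OV55666, the second Lv3NC and 1 KD553 library against their partners. A batch that the replicate number marks alike in all groups may be set aside as the whole source, since the deviations of the first libraries of Lv5NC and Lv3NC correlated negatively across genes (r = −0.462), as did those of OV55666 and Lv3NC (r = −0.383). A batch that the number marks only within a manipulation and its own control stays open. The first libraries of Lv5NC and OV55666 deviated together (r = 0.503), but this is the only such pair whose numbers agree between titles and descriptions, and a positive sign in 1 pair is no evidence against chance. For Lv3NC and KD553 r was 0.444 by the column names, whose numbers match the titles of the samples but not their descriptions. Such a batch would be balanced between a manipulation and its control and would add to the spread within groups. Unequal scaling is argued against by the component's share of 49.6% after quantile normalization. A culture or library batch that crosses the numbers stays open too, because the labels give none, and no biological explanation was tested.

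The near absence of epithelial RNA in cells that the labels call mammary gland cells could have a technical source. Of the luminal markers 94.4% have a row in the table, which argues against missing rows for that list. Only 10 of 14 basal or myoepithelial markers and 10 of 19 milk protein genes have one. A row also does not show that reads were assigned to it correctly, so faulty annotation stays open. The hypothesis that the cultures held mostly mesenchymal cells needs low epithelial markers with high fibroblast markers. The highest FPKM of EPCAM, CDH1, KRT8 and KRT18 in any library was 0.51, while all 12 fibroblast markers were above 1. These values raised the hypothesis, so they are no separate test of it. Epithelial cells that changed type in culture cannot be told apart from cells that were mesenchymal from the start. Among the keratin genes KRT7, KRT8, KRT14, KRT18 and KRT19 the highest level in any library was 0.61 FPKM (KRT7). The listed basal keratin genes KRT5, KRT15 and KRT17 have no row under their symbol. No library from before culture was analysed here.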
